A study of Homo sapiens with 4 samples.

How the data were processed

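Cells of 4 human melanoma lines were profiled with droplet-based 3' RNA sequencing, 1 library per line. Per the labels' protocols, cells were washed, suspended and loaded with the Chromium Single-cell 3' Reagent Kit, version 2, which marks each captured RNA molecule with a cell barcode and a unique molecular identifier (UMI). Such libraries read only the 3' end of transcripts, so they measure gene levels and not isoforms. Per the submitters' processing notes, Cell Ranger 3.0.0 and Seurat 3.0 were used with the builds hg19 and mm10; which step used which build is not given in the sources used here. No gene name in the table contained hg19 or mm10 as a species mark, and mouse-style spelling was not checked.

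The authors deposited a table of UMI counts per gene and cell, with 19238 genes and 8173 cells, and a second table of the same cells on a natural log scale. Recomputing the deposited natural log values as the log of 1 plus 10000 times a cell's count over its total gave the same numbers to within 1e-12, so only the counts were used. Every cell in the tables had 3001 to 6999 detected genes and at most 19.9% mitochondrial UMIs. These limits lie at round values (3000, 7000 and 20%), as a filter would leave them, and no source used here states the filter. Cells with many genes, doublets among them, would have been removed by such a limit. A second entry, marked by a numbered ending, existed for 18 symbols; these entries were kept apart and left out of the ranking of genes.

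Cell names consisted of a barcode and a suffix from 1 to 4, the form in which Cell Ranger writes cells of several libraries joined in 1 table. Nothing in the names, labels or files tied a suffix to a line, and no line was inferred from expression or order. The planned comparisons of each subline with WM239A, of the brain with the lung sublines and of both brain sublines were therefore not made. A fallback fixed before the data were examined makes no comparison between lines and describes only clusters of the pooled cells. No set was tied to a line, but the 4 barcode sets were also described as unlabelled samples, which goes beyond that fallback. That step was chosen after the cell names had been seen.

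For each set, counts were summed over cells and divided by the set's total (CPM). Between 71182648 and 71915542 UMIs were summed per set. Genes with at least 10 CPM in 1 or more sets (7421) were compared on the log2(CPM + 1) scale, which understates the ratio of weakly expressed genes, and a difference of 2-fold was used to describe size. No test of expression between sets was run and no p-value computed, because cells are not replicates and each set is 1 sample. Intervals on CPM are exact Poisson intervals, those on ratios of CPM exact conditional binomial intervals and those on shares of cells exact binomial (Clopper-Pearson) intervals, all at 95% and all covering counting error only. The count of genes 2-fold apart was tested on 4 simulated sets of 19238 genes, drawn with Poisson noise from the pooled profile with 200.0 genes changed in 1 set. Of 67 genes changed 1.5-fold 0 were counted, of 67 changed 3-fold 67, of 66 changed 4-fold 66, and of 6785 unchanged genes 0. Changed genes had a mean of at least 10 CPM and were scored as 1 set against every other set. No variation between libraries was simulated, so these counts check the calculation only.

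Genes were named by a rule adapted to the sets after the cell names had been seen, since the rule fixed earlier referred to lines. Among genes with at least 50 CPM in a set, those named were the 8 farthest above and the 8 farthest below every other set, for each set. Mitochondrial, ribosomal protein and clone-named genes were left out. To these were added up to 4 members of each list with the widest span and always MITF, SOX10, AXL, NGFR and EDNRB. Further list members named for contrast (PMEL, MLANA, HLA-E, S100A11) were chosen after their values were seen. The 33 gene lists were fixed before the data were examined. A list member was called measured if it had at least 10 CPM in 1 or more sets. A member may therefore enter through 1 set alone. A list's value in a set is the median over its measured members of log2(CPM + 1) minus the gene's median over the 4 sets, placed among 10000 random lists of equal size matched on mean expression in 10 bins. That percentile describes these libraries only.

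Cell cycle phases were assigned with scanpy 1.11.5 from S and G2M gene scores after each cell had been thinned to 10000 UMIs. The 6, 1, 1 and 1 cells of sets 1 to 4 with fewer UMIs were left out of that step. Clusters came from Leiden clustering at resolution 0.5 on 30 principal components of 2000 variable genes with 15 neighbours, with distances rounded so that repeated runs give the same clusters. Scrublet, run per set with an expected share of 6%, called 26 of 8173 cells doublets (0.318%), under 0.5%. The caller is taken not to have worked, so doublets were left in. Free RNA was not removed. Some genes of the lists are not reported here. Chromosome, order, GC content and length of genes were taken by symbol from GENCODE v29, whose build (GRCh38) is not that of the deposited files, so no coordinates are given. Of the 7421 genes, 6964 (93.8%) matched.

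Alternatives, chosen for the barcode sets after seeing the data but taken from those planned for the lines, were TMM scaling (edgeR 4.0.16), median-ratio scaling (DESeq2 1.42.0), the mean of each cell's CPM, no filter on low genes or 50 CPM, a pseudocount of 10 CPM, thinned cells, G1 cells, and totals without mitochondrial and ribosomal genes. Cells were also left out if called doublets, above 10% mitochondrial UMIs or under 1000 genes (no cell had so few), with 6500 or more genes or with the profile of another set. The other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3.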

Results

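Single-cell 3' RNA sequencing was used to profile WM239A, a human melanoma line that the labels call poorly metastatic, and 3 highly metastatic sublines derived from it. The sublines were 113/6-4L, labelled by lung metastasis, and 131/4-5B1 and 131/4-5B2, both labelled by brain metastasis. Each line was 1 library, so no line had a replicate. The question posed by this design is how the transcriptomes of the metastatic sublines differ from that of the parental line and between target organs. The deposited count table held 19238 genes and 8173 cells. Its cell names ended in 1 of 4 suffixes, which parted the cells into 4 sets, here called barcode sets 1 to 4, and nothing in the names or labels tied a suffix to a line. No comparison between lines was therefore made, and no set was given a line's name. The values below describe the 4 unlabelled sets one by one, always in the order of sets 1 to 4 unless a set is named.

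The sets held 2121, 1779, 2140 and 2133 cells. Their total UMI counts (unique molecules counted) were 71617986, 71915542, 71444474 and 71182648, so the lowest total was 99.0% of the highest. The median cell had 33556, 41131, 33152.5 and 33390.0 UMIs and 5281, 5697, 5190.5 and 5215 detected genes. Expression is given as CPM, a gene's UMIs summed over a set's cells per 1000000 UMIs of that set. Intervals are exact 95% intervals, and they cover counting error only, since no set was replicated. Fold values between sets are ratios of these summed counts and compare the cells of the sets, not conditions.

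PMEL, a structural protein of the melanosome, stood at 2201, 2766, 4883 and 4496 CPM, and MLANA, a melanocyte antigen, at 2182, 2203, 2795 and 2667 CPM. MITF, the lineage's master transcription factor, was at 257, 196, 267 and 261 CPM, and SOX10, a neural crest transcription factor upstream of it, at 70.4, 58.2, 61.5 and 65.4 CPM. AXL, a receptor kinase of the undifferentiated melanoma state, was barely detected, with 83, 8, 1 and 1 UMIs in total, and NGFR, the low-affinity nerve growth factor receptor, reached 8.08 CPM in set 1 and at most 0.431 CPM elsewhere. The sets differed in single pigment genes. Of 18 measured members of the melanocytic differentiation list, 7 spanned at least 2-fold over the sets, and set 2 had the lowest list median, -0.31 on the log2 scale relative to each gene's median over the sets. GPR143, a melanosomal receptor, stood at 5.80 CPM in set 2 against 23.8, 63.0 and 51.8 CPM in sets 1, 3 and 4. DCT, an enzyme of melanin synthesis, was also lowest in set 2 (242, 151, 421 and 327 CPM). APOE, a secreted lipid carrier, was lowest in set 1 (412, 846, 1444 and 1210 CPM), 3.50-fold below set 3 (3.46 to 3.55), and CITED1 was highest there, with 23.8 CPM in set 1 and 4.71 to 6.31 CPM in the others. EDNRB, the endothelin B receptor, stood at 32.0 CPM in set 2 and between 74.6 and 86.6 CPM in the other sets.

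Of 7421 genes that reached 10 CPM in at least 1 set, 434 (5.85%) differed at least 2-fold between the highest and the lowest set on the log2(CPM + 1) scale, and 129 differed 4-fold. Set 1 had the most genes of its own. Its CPM was 2-fold higher than in every other set for 75 genes and 2-fold lower for 78. The same counts were 14 and 11 genes for set 2, 3 and 0 for set 3, and 0 and 0 for set 4. Sets 3 and 4 were 2-fold apart in only 4 genes, so neither could have more than 4 such genes of its own. Set 4 was 2-fold apart from set 1 in 306 genes and from set 2 in 104. Between sets 1 and 3, 323 genes were 2-fold apart, the most of any pair. Between sets 3 and 4 there were 4, all higher in set 3, which were VCX3B, VCX, NUPR1 and SLC7A11. With a pseudocount of 10 CPM the count over all sets was 198, and with no filter on low genes it was 1012.

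**Figure D1:**
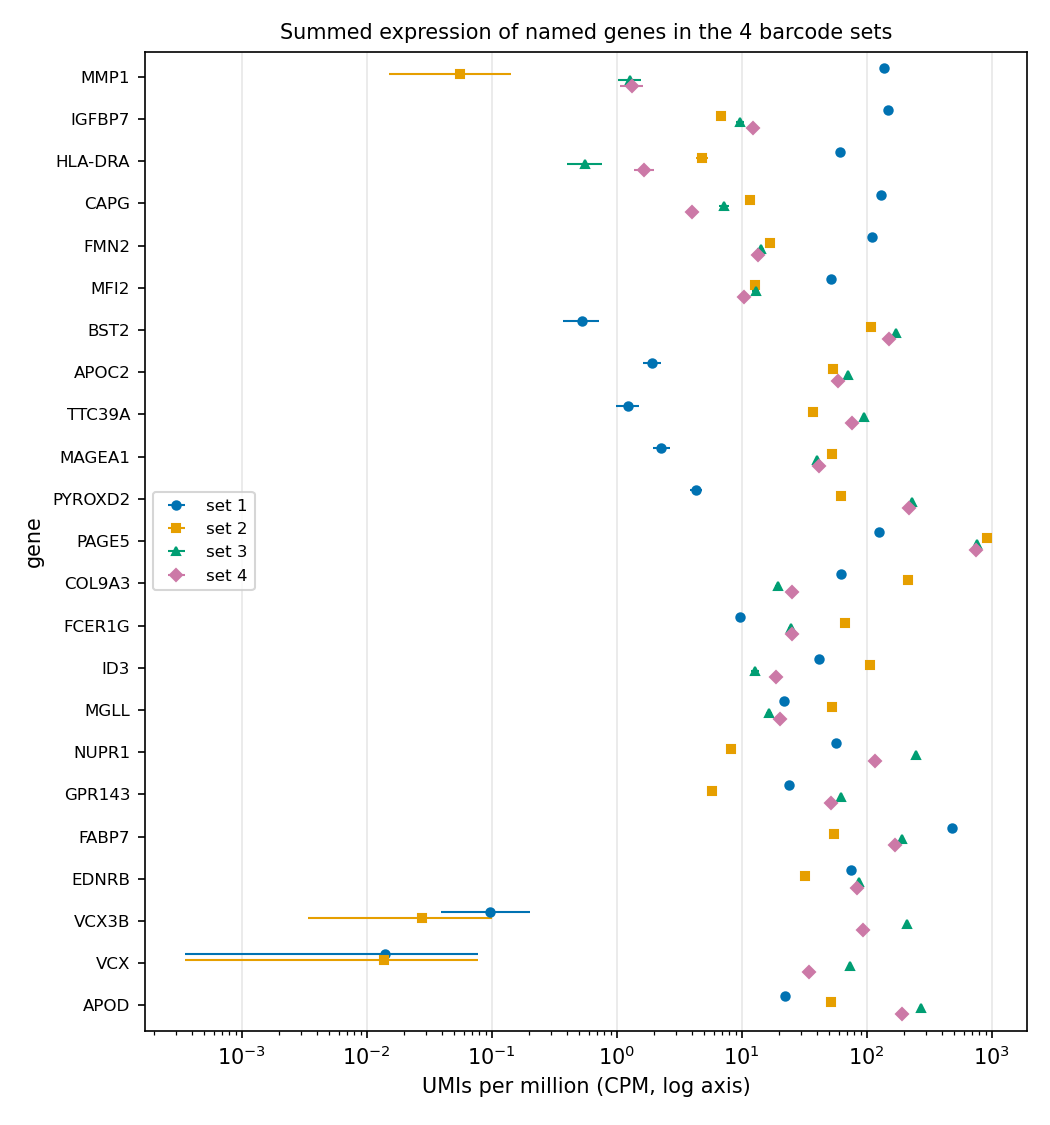
CPM (horizontal log axis) of counts summed over the cells of each barcode set, for 23 genes among those with the widest gap between 1 set and every other set. Points are the 4 sets and bars are exact 95% Poisson intervals, hidden by the point where narrow. MMP1 stands at 139 CPM in set 1 and at most 1.32 CPM elsewhere, and BST2 at 0.531 CPM in set 1 and 109 to 172 CPM elsewhere.

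List medians are measured from each gene's median over the 4 sets. Over all compared genes, single-gene values on this scale had a standard deviation of 0.43 in set 1 and 0.22, 0.18 and 0.14 in sets 2 to 4. Genes in general thus lay farther from 0 in set 1. Among the gene lists, the MHC class II pathway had the widest span of list medians over the sets. All 5 measured members of the MHC class II pathway, which presents peptides to CD4 T cells, spanned at least 2-fold, with list medians of 2.59, 0.64, -1.09 and -0.64. The list had 9 genes with deposited counts, and of the measured ones HLA-DRA, HLA-DMA and HLA-DPB1 reached 10 CPM in set 1 only. HLA-DRA, a class II chain, stood at 61.5, 4.85, 0.560 and 1.66 CPM, a ratio of 109.8 between sets 1 and 3 (80.5 to 154). CD74, the invariant chain, stood at 126, 57.6, 6.79 and 11.9 CPM, and HLA-DMA, which loads peptides, at 17.8, 3.32, 0.448 and 0.773 CPM. In cells thinned to 10000 UMIs, CD74 was seen in 54.8%, 35.6%, 5.52% and 8.40% of cells, and in 78.9%, 70.7%, 14.2% and 20.4% at the deposited depth. No cell type lacking CD74 was present to measure the background from free RNA. The class I pathway was lowest in set 1, with a median of -0.52 in set 1 and between 0.01 and 0.08 in the others. HLA-B and HLA-C, which are class I chains, were lowest in set 1, and HLA-C stood at 146, 238, 275 and 292 CPM, while the non-classical HLA-E was highest there (91.6, 58.9, 87.3 and 80.3 CPM). BST2, an interferon-induced membrane protein that tethers budding virus, was nearly missing from set 1, at 0.531 CPM (38 UMIs) against 109, 172 and 151 CPM. Of 11 measured interferon-stimulated genes, BST2 and ISG15 spanned 2-fold and the others did not. ISG15 was highest in set 2 (18.4, 44.9, 18.8 and 23.9 CPM). CASP1, the inflammasome protease, stood at 3.63, 25.9, 84.0 and 73.2 CPM.

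Among proteases and adhesion receptors, set 1 had the list medians farthest from 0, which was not so for matrix genes. Values over all compared genes were also spread most widely in set 1. MMP1, the interstitial collagenase, stood at 139 CPM in set 1, 0.0556 CPM (4 UMIs) in set 2 and 1.27 and 1.32 CPM in sets 3 and 4, so set 1 was 104.9-fold above set 4, the nearest other set (85.7 to 130.0). PLAT, tissue plasminogen activator, stood at 51.9, 16.6, 26.3 and 21.8 CPM, and the 17 measured proteases and inhibitors had a median of 0.50 in set 1 and between -0.05 and -0.01 in the others. Among 20 measured adhesion receptors, 10 spanned 2-fold. In set 1, 7 were 2-fold above the median of the other sets and 1 was below it. CDH2 (N-cadherin) stood at 24.1, 4.06, 2.63 and 4.52 CPM and ITGA4, an integrin subunit, at 27.6, 11.8, 7.29 and 9.05 CPM, while CDH3 (P-cadherin) ran the other way, at 0.195, 8.68, 17.97 and 14.3 CPM. FN1 (fibronectin) was at 418, 179.6, 243 and 211 CPM and TNC (tenascin C) at 38.7, 33.7, 14.6 and 16.8 CPM, although the 11 measured matrix genes together had medians between -0.08 and 0.06. COL9A3, a collagen IX chain, was highest in set 2, at 61.9, 216, 19.4 and 25.2 CPM. The undifferentiated or invasive list had 6 measured members and a median of 0.66 in set 1, led by CTGF (15.9, 7.27, 2.80 and 3.15 CPM) and TGFBI (83.5, 52.6, 31.2 and 42.7 CPM). The list had 19 genes with deposited counts, so most, AXL among them, stayed under 10 CPM in every set. CTGF reached 10 CPM in set 1 only.

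Several calcium-binding S100 genes and all 3 measured metallothioneins were highest in set 1. S100B, a melanoma serum marker, stood at 2864, 1445, 1315 and 1283 CPM, S100A6 at 1549, 1403, 702 and 800.1 CPM and ANXA1, an annexin, at 183, 111, 44.5 and 50.9 CPM. MT2A, a metallothionein, was at 2718, 1906, 1291 and 1381 CPM and MT1E at 36.9, 15.7, 11.4 and 9.22 CPM. The S100 family list, with 8 measured members, had a median of 0.53 in set 1 and the metallothionein list 0.74, but S100A11 was lowest in set 1 (565, 852, 834 and 859 CPM). MGST1, a glutathione transferase, was at 404, 155, 125 and 157 CPM, and PRDX1, a peroxidase, was instead highest in set 2 (1295, 1882, 922 and 983 CPM).

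Hypoxia response genes (14 measured) had a median of 0.31 in set 1 and between -0.08 and -0.01 in the others, with BNIP3L, a mitophagy receptor, at 106, 44.0, 62.8 and 55.6 CPM. Glycolysis genes (16 measured) had a median of 0.21 in set 1, and only SLC16A3, a lactate exporter, spanned 2-fold (192, 107, 40.3 and 45.9 CPM). None of the 26 measured nuclear-encoded oxidative phosphorylation genes spanned 2-fold, and their median was highest in set 2 at 0.12. That lay at percentile 99.98 of 10000 random lists matched on expression, but several other lists, though not all, lay about as far out. The cholesterol synthesis list was at percentile 99.97 in set 4 and the mitochondrially encoded list at 0.02 in set 1. The percentile therefore does not set the oxidative phosphorylation list apart. The 12 measured mitochondrially encoded genes had a median of -0.25 in set 1, although MT-ND6, the member with the widest span, was highest there (106, 71.5, 62.9 and 72.4 CPM). The median mitochondrial share of a cell's UMIs was 5.41%, 6.73%, 7.12% and 6.83%. In the ER stress and amino acid response list, 6 of 21 measured genes spanned 2-fold and the medians were 0.35, -0.24, 0.09 and -0.12. SLC7A11, the cystine importer, stood at 18.2, 3.25, 7.46 and 2.35 CPM, and TRIB3, a stress-induced pseudokinase, at 114, 38.3, 100.4 and 59.8 CPM. NUPR1, a stress-induced chromatin protein, ran from 8.20 CPM in set 2 through 56.9 CPM in set 1 to 117 CPM in set 4 and 249 CPM in set 3. None of the 19 measured cholesterol synthesis genes spanned 2-fold, and their medians were -0.15, -0.07, 0.05 and 0.08.

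ID1 and ID3, inhibitors of differentiation induced by BMP and TGF-beta signals, were highest in set 2, with ID1 at 25.8, 38.1, 4.48 and 5.90 CPM and ID3 at 41.7, 106, 12.8 and 18.8 CPM. CCND1 (cyclin D1) was lowest in set 1 (416, 769.9, 914 and 931 CPM), whereas DUSP4 and DUSP6, phosphatases induced by MAPK signalling, were highest there, and DUSP6 stood at 110.2, 92.6, 71.8 and 72.2 CPM. No measured p53 response gene of 11 spanned 2-fold. Of the cytokine and NF-kB list, CXCL1 (9.91, 1.42, 10.1 and 6.79 CPM) and IL8 (16.5, 3.73, 13.6 and 7.07 CPM) were lowest in set 2. The testis antigens MAGEA1 (2.28, 52.4, 40.1 and 41.4 CPM) and PAGE5 (126, 919, 769 and 747 CPM) were lowest in set 1, while MAGEA6 was highest there (13.4, 3.87, 4.70 and 5.58 CPM). VCX3B and VCX, X-linked testis genes with near-identical copies among which reads could have been split, stood at 212 and 73.1 CPM in set 3 and 94.0 and 34.6 CPM in set 4. In sets 1 and 2, VCX3B had 7 and 2 UMIs and VCX had 1 and 1. Among 7 measured genes reported in brain metastasis, APOD, a lipid carrier, had the widest span, at 22.2, 51.8, 270.4 and 191 CPM, and HBEGF, a growth factor, stood at 3.76, 6.37, 9.60 and 10.7 CPM, while PCDH7, a protocadherin, was highest in set 1 (21.4, 9.48, 14.1 and 12.8 CPM).

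**Figure D2:**
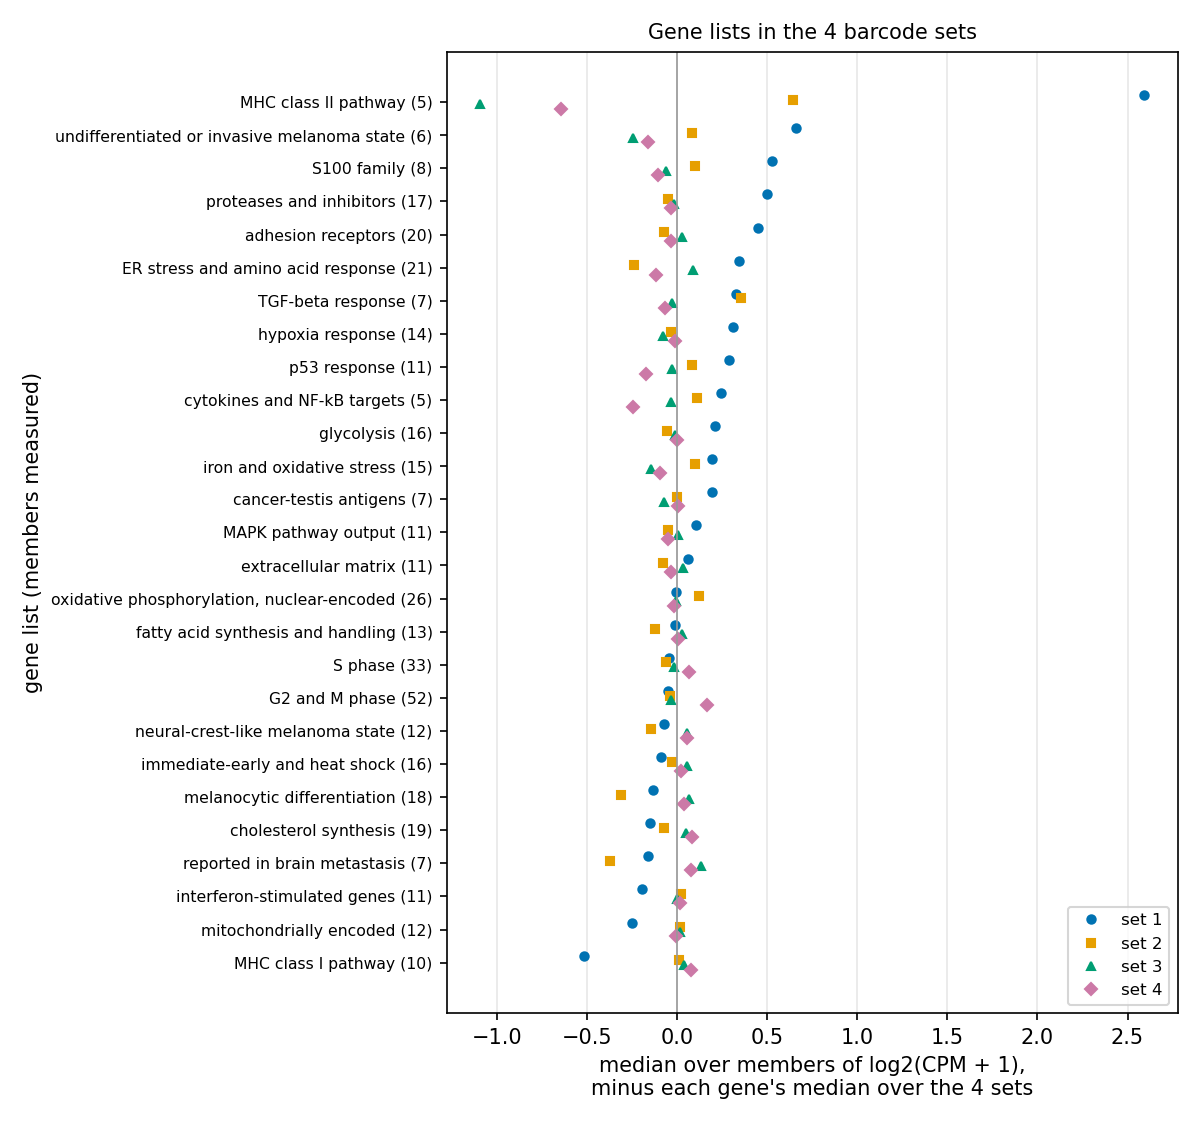
Median over each gene list's measured members (number in brackets) of log2(CPM + 1) minus the gene's own median over the 4 barcode sets, with 1 point per set. The MHC class II list spreads from 2.59 in set 1 to -1.09 in set 3, and the class I list has its lowest value, -0.52, in set 1.

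Markers of other cell types were scarce. No endothelial marker reached 10 CPM in any set. LUM (lumican) was the only fibroblast marker that did, at 12.7, 2.18, 0.182 and 0.407 CPM, and CD68 was the only immune marker, at 29.3, 34.1, 38.4 and 37.9 CPM. KRT18, a simple epithelial keratin, stood at 101, 152, 101 and 109 CPM, and MBP, a myelin gene of glia, was highest in set 1 (314, 183, 192 and 196 CPM).

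Cell cycle phases were assigned to cells thinned to 10000 UMIs. Cells assigned to S or G2M made up 62.5% of set 1 (60.4% to 64.5%), 73.1% of set 2 (71.0% to 75.2%), 70.4% of set 3 (68.4% to 72.3%) and 79.7% of set 4 (77.9% to 81.4%). At the deposited depth the shares were 61.5%, 72.7%, 70.4% and 80.7%. The 52 measured G2 and M genes had a median of 0.17 in set 4 and between -0.05 and -0.03 in the others. MKI67, a proliferation marker, stood at 40.8, 51.6, 52.5 and 65.9 CPM and AURKB, a mitotic kinase, at 72.2, 83.4, 94.7 and 113 CPM. Other members were highest in set 1, with FAM64A at 42.2, 31.6, 26.2 and 32.5 CPM and the cyclin CCNB2 at 50.9, 39.8, 32.8 and 41.5 CPM. Phase calls alone do not measure division rate, and free RNA from other cells was not removed.

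**Figure D3:**
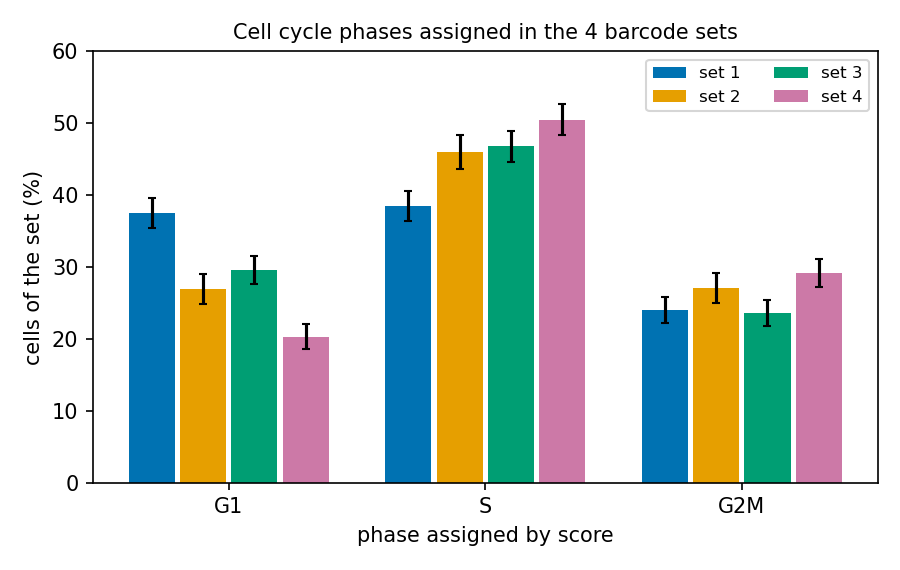
Percent of each barcode set's cells (vertical axis) assigned to G1, S or G2M by score after thinning to 10000 UMIs. Bars are the 4 sets with exact 95% binomial intervals. Set 4 has the fewest cells in G1, 20.3%, and set 1 the most, 37.5%.

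Clustering of the pooled cells at the deposited depth gave 9 clusters of 53 to 2066 cells, which are named by number because no cluster was led by markers of another cell type. By phases assigned at the deposited depth, without thinning, every cell of clusters 2 (564 cells) and 8 (1455 cells) was in S or G2M. Cluster 1 (1334 cells) had 42.7% in these phases. Cluster 3 (244 cells) had a median mitochondrial share of 10.2%. Cluster 4 (53 cells) had a median of 16079 UMIs and a mitochondrial share of 1.02%. The borders between clusters were not fixed. With 10 other random seeds the adjusted Rand index to these clusters lay between 0.753 and 0.922, where 1 is an identical grouping.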

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

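Comparing the 4 barcode sets with one another on 9 measures of size and composition was chosen after the data were seen. Set 2 stood apart from the other 3 sets in its number of cells, 1779 against 2121 to 2140, and in its median UMIs per cell, 41131 against 33152.5 to 33556. The gap to the nearest set was 0.947 and 0.949 of the whole range, above the 95% critical value of Dixon's test for 4 samples. For 1 measure, chance passes that value in about 1 of 20 groups. With 9 measures compared, a pass in some measure is likelier than that. The sets are unlabelled samples and not replicates of a group. Total UMIs were close (71182648 to 71915542), so the set with fewer cells had deeper cells, and the flagged measures are not independent of each other. No explanation was tested.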

How the results depend on the processing

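The alternatives for the barcode sets were chosen after seeing the data, and those for phases and clusters before. Not run, because no cell was tied to a line, were the comparisons of lines, the edgeR quasi-likelihood test by phenotype and the correlation of subline changes with its split parental cells. No paired analysis was possible because each line is 1 library with no replicate number. Of 195 alternative counts of genes, 159 stayed within 1.5 times the value reported and 36 did not, of 724 list medians 714 moved less than the spread of the list's members and 10 more, and of 594 log2 ratios of named genes 476 stayed within counting error, 117 moved beyond it and 1 reversed. Without a filter on low genes, 1012 genes differed 2-fold over the sets against 434, and between sets 1 and 2, 1 and 3, 1 and 4, 2 and 3, and 2 and 4 there were 539, 705, 680, 269 and 203 against 236, 323, 306, 130 and 104. With a minimum of 50 CPM these 6 counts were 126, 61, 95, 88, 35 and 32, since fewer genes are counted, and with a pseudocount of 10 CPM, which shrinks ratios of low genes, 198, 94, 146, 128, 46 and 38. Between sets 3 and 4 the count of 4 became 2 with that pseudocount and 11 in G1 cells alone, where the cause was not tested. TMM scaling gave 416 genes over all sets. It moved the median of all genes in set 1 by -0.06 (log2), and leaving mitochondrial and ribosomal genes out of the totals raised it by 0.47, 0.51, 0.53 and 0.51 in sets 1 to 4. The G2M share of set 1 was 24.0% when thinned and 22.0% at the deposited depth. Counting cells with 2 or more UMIs over 5 G2M genes, a looser rule, gave 49.6%, 54.6%, 50.4% and 60.9% for sets 1 to 4 against 24.0%, 27.1%, 23.6% and 29.2%, with set 4 highest by both rules. Clusters numbered 5 at resolution 0.25 and 13 at resolution 1.0, against 9, and 9 with each of 10 other random seeds, chosen after seeing the data. The log2 ratio of PLK1, a mitotic kinase, in set 4 over set 2 was 0.34 and reversed to -0.14 in G1 cells, where the cause was not tested. Depth limits genes with few UMIs, such as MMP1 in set 2 and VCX in sets 1 and 2.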

Other observations

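The tests of library scaling, copy number, 1 library under 2 suffixes, exchanged barcodes and doublets, and the description of cells within and between sets, were chosen or changed after the values had been seen.

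Single genes varied between cells of 1 set by more than counting gives, for which the variance of thinned UMIs would equal the mean. In set 3, C11orf96 had a variance of 36.2 times its mean, the highest of the genes ranked, and CDKN1A, the p21 inhibitor of cell division, had 11.3 against 2.06 to 2.36 in the other sets. IL8, a chemokine, had 13.4 in set 1 and 14.6 in set 3. These 3 genes were higher in cluster 4, which has 53 cells, 8 of them of set 3, with C11orf96 at 859 CPM against 22.1 CPM in all other cells, IL8 at 367 against 8.92 and CDKN1A at 322 against 62.1, and how much of the spread within a set comes from these few cells was not measured. MALAT1, a nuclear RNA, and HIST1H4C, a histone of S phase, were among the highest in all 4 sets, between 23.1 and 29.6 and between 15.5 and 18.2. In set 1, MMP1 had 6.45, and it was seen in 41.8% of thinned cells (64.6% at the deposited depth), where a random spread of its UMIs over cells would give 73.8%. Class II genes were seen together in cells of each set. In sets 2, 3 and 4, HLA-DRA was seen in 4.90%, 5.93% and 9.50% of cells with CD74 and in 1.75%, 0.247% and 0.717% of the rest. In set 1, HLA-DRA was seen in 43.9% of cells with CD74 (41.0% to 46.8%) and in 14.6% of the rest (12.4% to 17.0%), and HLA-DPA1 in 41.2% and 15.2%. MMP1, which is no class II gene, was also seen more often in cells with CD74, in 46.5% (43.6% to 49.4%) against 36.1% (33.1% to 39.3%), a smaller difference, and BST2 in 0.690% (0.298% to 1.35%) against 0.524% (0.170% to 1.22%).

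The sets fell apart in clustering to different degrees. Counting each cell itself with its 15 nearest neighbours, 98.2% in set 1 and 96.8% in set 2 were of the cell's own set. In sets 3 and 4 the shares were 62.2% and 63.6%. Among neighbours alone, mixing would give 26.0% and 21.8% in sets 1 and 2. Counting the cell itself raises each observed share. In clusters 0 and 1, 772 of 774 and 1334 of 1334 cells were of set 1, 558 of 564 cells of cluster 2 and 1173 of 1190 cells of cluster 5 were of set 2, while clusters 6, 7 and 8 were shared by sets 3 and 4. In all, 47.3% of cells lay in clusters with at least 95% of cells from 1 set, and with 10 other random seeds, which moved the borders of clusters, the share was 46.6% to 47.4%. With 1 library in each set, a cluster of 1 set may reflect that library, and the share was 46.7% without S and G2M genes among the variable genes. No line is inferred from these groupings. Cluster 4, with a median mitochondrial share of 1.02%, held 6, 29, 8 and 10 cells of sets 1 to 4, and cluster 3 held 1, 4, 102 and 137.

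Genes of whole chromosomes were shifted together. Relative to each set's median gene, the 240 measured genes of chromosome 8 had a median of 0.27 on the log2 scale in set 1, those of chromosomes 10 and 13 had -0.26 and -0.24, and those of chromosome 18 had -0.19 in set 2, each outside all 10000 random lists matched on expression. That alone does not set these shifts apart. Of 84 chromosome and set medians, 58 lay outside the central 95% of random lists, some with far smaller shifts (chromosome 1 in set 3, 0.012). Chromosome 19 was shifted in every set, by -0.17, -0.10, 0.12 and 0.09 in sets 1 to 4. Scaling moves all chromosomes of a set alike, so the chromosome 8 to 10 difference of set 1, at the lowest 0.53 over 3 scalings, was bound to stay and is no test of it. Removing the trend on GC content and length left chromosome 8 at 0.25, which argues against that trend as the whole cause. Leaving out genes 2-fold apart between sets left it at 0.26, but a median resists a few genes, so this is no test of them. In set 1, 82.1% of the chromosome 8 genes lay above the set's median gene, so the shift was not confined to a few. Medians of the first and last part of each chromosome's genes correlated at 0.96 over 21 chromosomes and 4 sets (values of a set are not independent). A candidate explanation is that the 4 cell populations differ in chromosome copy number; DNA was not measured, and the hypothesis was found and tested on the same data.

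Sets 3 and 4 were closest, with a correlation across genes of 0.998 (genes are not independent replicates) against 0.9498 to 0.983 for other pairs. They shared 8 barcodes where chance gives 6.19, which argues against 1 library split under 2 suffixes. The sum of squared log2 ratios between them was 4.92 times the highest of 100 random relabellings of their cells, above the bound of 2 times set beforehand, which argues against the sampling of cells as their only difference. With 1 library in each set, this does not part differences of library preparation from differences between the cells. No biological explanation was tested, since no group in the labels can be set against a barcode set.

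A few cells resembled another set. By their counts of 434 genes, 138 cells (1.69%, 1.42% to 1.99%) were closer to a set other than their own, 61 of them in set 4 with the profile of set 2. Sets 3 and 4 were taken as 1 profile, so cells of either that resembled the other were not counted. The barcodes of the 138 cells argue against exchange between libraries, since 0.725% of these cells carried a barcode also present in the set they resembled. Of these cells 41.3% (32.996% to 49.995%) had more UMIs than their set's median. A bound on UMIs first used, 0.5, would have argued against doublets of cells from 2 sets by a narrow margin. That bound was dropped after the value was seen, because cells with 7000 or more genes are not in the table. If each suffix marks a separate library, a droplet holds cells of 1 set only. Doublets of 2 sets could then not form, so UMI totals are no test of them. Why these cells resembled another set was left open. The median fitted share of the other profile was 0.61, which the selection itself keeps high, and in 12 cells it was above 0.8.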
